A study of Mus musculus with 2 samples.

How the data were processed

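Total RNA from the heart of B6CASTF1/J male mice aged 10 days was measured in 2 libraries of 1 group. Per the labels, the RNA was purified with a kit for animal tissue, each library started from 300 ng, ribosomal RNA was reduced, strand was kept and ERCC spike-in RNAs were added. Each library was treated as 1 animal, and replicate numbers were taken from the labels. The labels number the males separately, although both point to the same donor record.

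Each library came with a gene table, a transcript table from the same quantification, and a transcript table from another quantification. Per the file headers and the deposited notes, the authors worked on the mm10 build with the GENCODE M21 annotation. The first quantification was derived from alignments to the transcriptome and the other directly from reads. The names and versions of the programs were not given in the sources used here. The column layouts are those of RSEM and kallisto. Whether the counting used strand was not stated in them, so overlapping genes on opposite strands are uncertain. The authors' gene and transcript tables hold expected counts, which need not be whole because reads that fit several genes are divided among them, and the other table holds estimated counts in the same sense. The same deposited tables hold TPM, scaled by the authors to a constant sum over all rows of a file, spike-ins included. They also hold FPKM, per the file headers, which was used here as an alternative. The deposited credibility bounds of TPM were not used here. All reads were assigned to a B6-based reference, and reads from CAST alleles that differ from it could be lost alike in both libraries.

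The gene tables held 55536 annotated genes, all of which matched a symbol in GENCODE M21, whose identifiers are those of the files and from which symbols, biotypes and coordinates were taken. They also held 96 ERCC controls, a phiX control with 0 counts, and 26248 rows that name no gene. Those rows held 3.89 counts in replicate 1 and 3 in replicate 2 and were left out of library sizes and comparisons. Where a symbol had several identifiers, the one with the highest mean TPM was used. The total expected count was 38851514 in replicate 1 and 37907585 in replicate 2, and the other quantification gave 38688448 and 37361816. A floor of 3 counts equals 0.0772 and 0.0791 CPM of the total. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

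From these files, levels were summarised as the mean and SD of TPM over 2 animals, and a gene was called detected at 1 TPM or more in both. Correlations used log2(TPM + 1). For comparisons between the animals, expected counts were rounded to whole numbers and scaled by edgeR's TMM factors, 0.5 was added to each count, and the log2 ratio was taken as replicate 2 over replicate 1. Exact 95% Clopper-Pearson intervals of the ratio were computed from the counts. A gene was counted as over 2-fold at a mean count of at least 50, a ratio over 2-fold and an interval that left out 1. No test across animals was possible with 1 library each, and no p-value across genes was computed. The biological coefficient of variation is the square root of edgeR's common dispersion with an intercept-only design, over genes with at least 10 counts in both libraries. For gene lists, members with a mean count of at least 10 entered, lists with fewer than 3 such members were left out, and the median ratio was placed among 10000 random lists drawn from the same of 20 bins of mean count. Maturation pairs were log2 ratios of TPM with a pseudocount of 0.1, and a pair was counted when both animals exceeded 2-fold in the same direction. Shares of counts used the total of all rows. For pseudogenes among the 20 highest genes, words of 31 bases shared with mitochondrial genes were counted in the annotated transcript sequences.

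The gene lists, pairs, isoform genes, tests and alternatives were fixed before the data were examined. So was the rule for named genes: all members of the pairs, the 20 genes with the highest mean TPM, the 3 highest members of each list and defining members under 1 TPM, the 10 genes at each end of the ratios among those over 2-fold, the 3 members with the largest ratio in each list that stood apart, and isoform genes with a dominant share under 50% or a different dominant transcript between quantifications, plus Ttn, Tnnt2, Tpm1, Camk2d, Mef2c, Pkm and Fn1. A few other list members are named in the text and were chosen after their values were seen: Egr1, Junb, Kcna5, Arntl, Nr1d1, Nppb, Adipoq, Sln, the other Rnu3a, Neat1 and the smooth muscle and pericyte genes. The second adipocyte list and the sinus node list were written after a first look at the genes with the largest ratios, none of them in either list, and before the values of their members were looked at. The sinus node genes are a part of the fixed conduction list, so their median is not separate evidence from that list. A few genes that these rules and tests name are not reported here. The marker lists give levels in bulk RNA, not cell shares. Alternatives covered other scalings (DESeq2 size factors, totals without mitochondrial genes and spike-ins, spike-in totals), other minimums and pseudocounts, the other quantification, FPKM, CPM, each member of a list left out and each replicate left out. Restriction to protein-coding genes and rescaling of TPM to nuclear protein-coding genes were added after seeing the data.

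The procedures were tested on simulated data. In 2 simulated libraries with the means and depths of the real ones, 13212 genes entered the step. Of the genes changed 3-fold, 100% were counted as over 2-fold, and of those changed 1.5-fold 5%, while 0.0845% of 13014 unchanged genes were counted. Of 200 random lists of 12 unchanged genes 4.5% stood apart. A simulated coefficient of variation of 0.1 was recovered as 0.0998 from 16258 genes. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.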

Results

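Total RNA was sequenced from the hearts of male mice at 10 days of age. The animals were B6CASTF1/J, the first-generation hybrid of a B6 laboratory mouse and the wild-derived CAST mouse. There were 2 libraries in 1 group, called replicate 1 and replicate 2 after their labels. The labels count them as separate biological replicates from separately numbered males, although both point to the same donor record, so the spread below is that between these 2 samples. Each library was stranded, reduced in ribosomal RNA, made from 300 ng of RNA and spiked with ERCC control RNAs. The total expected count was 38851514 in replicate 1 and 37907585 in replicate 2. With 1 group there was no treatment, stage or genotype to compare. The data give the levels of genes in the heart shortly after birth, the balance between genes that replace each other as the heart matures, and the differences between the animals.

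In the first of the deposited quantifications, the most abundant RNAs came from the mitochondrial genome, from short structural RNA genes and from the contractile apparatus. The large mitochondrial rRNA mt-Rnr2 (chromosome M, 1094 to 2675, mm10) stood at 96884 ± 794 TPM (transcript abundance scaled for length and depth; SD, n = 2), and the small one, mt-Rnr1, at 51781 ± 1764 TPM. Among mitochondrial mRNAs, mt-Co1, which encodes the catalytic subunit of cytochrome oxidase, reached 27367 ± 306 TPM, mt-Co3 11465 ± 362 TPM and mt-Cytb 11433 ± 350 TPM. Rn7sk, which restrains transcription elongation, was at 27698 ± 1536 TPM. This level holds for the first quantification only. The whole list of abundant noncoding RNAs, with Rn7sk in it, held 3.86% and 3.85% of TPM there. In the other quantification that list held 0.126% in replicate 1 and 0.148% in replicate 2. The signal recognition particle RNA genes Rn7s1 and Rn7s2 were each at 89229.5 ± 15654 TPM, and their counts were identical in either library (474952 and 645859), so the copies could not be told apart. The nuclear mRNAs with the highest levels were Myh6, the alpha myosin heavy chain of the adult mouse heart (chromosome 14, 54941921 to 54966927, minus strand), at 8464 ± 185 TPM and Myl2, the ventricular myosin light chain, at 7691 ± 292 TPM.

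Mitochondrially encoded genes held 22.6% of the expected counts in replicate 1 and 24.2% in replicate 2 (23.4% ± 1.16). Mitochondrial rRNA made up 14.6% and 15.9%, protein-coding genes 75.3% and 73.0%, and the 10 most abundant genes together 29.2% and 32.4%. The exact 95% binomial (Clopper-Pearson) interval of the mitochondrial share was 22.572% to 22.599% in replicate 1 and 24.213% to 24.240% in replicate 2. Such intervals cover counting error only, and the animals differed by far more than that. As a share of TPM the order was the opposite, with mitochondrially encoded genes at 25.4% in replicate 1 and 24.9% in replicate 2. A stretch of chromosome 1 holds the pseudogenes Gm28661, Gm29216, Gm10925 and Gm28437, which were among the 20 genes with the highest TPM. All 31-base words of Gm28661 also occur in mt-Co2, those of Gm10925 in mt-Atp6 and those of Gm28437 in mt-Co3, with 100% shared in each case, and 97.2% of those of Gm29216 occur in mt-Co1. Gm28661 was listed at 21880 ± 1319 TPM and mt-Co2 at only 369 ± 16.1 TPM, so these levels depend on how reads were divided between near-identical sequences and are uncertain. Another of the 20 was Gm26917, annotated as a lincRNA on chromosome 17, at 8571 ± 1473 TPM, and the origin of its reads was not examined.

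At a minimum of 1 TPM in both libraries, 12710 genes were detected, of which 11546 were protein-coding. Replicate 1 alone had 13308 genes and replicate 2 had 13004. Across genes, log2(TPM + 1) in the animals correlated with a Pearson coefficient of 0.993 and a Spearman coefficient of 0.929, where genes are not independent replicates. The biological coefficient of variation between the animals, estimated by edgeR from 16166 genes, was 0.147.

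Of the fixed lists, the mitochondrially encoded proteins had the highest median TPM, followed by the sarcomere genes. All 25 sarcomere genes were detected in both hearts, with a median of 659 ± 13.9 TPM, and the list took 4.76% and 4.40% of all TPM. After Myh6 and Myl2, its highest member was the cardiac actin Actc1 at 6345 ± 845 TPM. All 13 calcium handling genes were detected (median 128 ± 8.50 TPM), led by the sarcoplasmic reticulum pump Atp2a2 at 3075 ± 270 TPM, its inhibitor phospholamban (Pln) at 1830 ± 9.26 TPM and calsequestrin (Casq2) at 416 ± 21.7 TPM. Ion channels and gap junctions were detected for 17 of 19 members, with connexin 43 (Gja1) at 175 ± 30.7 TPM and the channel subunit Kcnip2 at 48.9 ± 2.29 TPM. Cardiac transcription factors and coactivators were detected for 16 of 17 members, led by Ppargc1a (90.6 ± 1.91 TPM), Mef2a (81.0 ± 1.32 TPM) and Tbx20 (67.6 ± 11.4 TPM), while Hand1, a factor of the early left ventricle, was at 0.035 ± 0.00707 TPM with 2 counts in each library. The receptor list, with 15 of 16 members detected, was led by the thyroid hormone receptor Thra (70.6 ± 1.58 TPM), the insulin receptor Insr (53.6 ± 0.502 TPM) and the glucocorticoid receptor Nr3c1 (32.5 and 27.5 TPM).

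Oxidative metabolism was strongly represented. All 13 mitochondrially encoded protein genes (median 6508 ± 141 TPM) and all 20 nuclear genes of oxidative phosphorylation (median 509 ± 53.7 TPM) were detected, the latter led by the ATP synthase subunits Atp5b (3054 ± 201 TPM) and Atp5a1 (1450 ± 112 TPM) and by Cox4i1 (1586 ± 85.5 TPM). The median of the nuclear list was 885 ± 62.5 TPM in the other deposited quantification. Fatty acid uptake and oxidation, with 22 of 22 members detected, had a median of 362 ± 3.19 TPM. Its leading members were the fatty acid binding protein Fabp3 at 3035 ± 36.2 TPM, the thiolase Acaa2 at 717 ± 40.4 TPM and the fatty acid transporter Cd36 at 668 ± 39.1 TPM. Glycolysis, with 18 of 18 detected, had a median of 227 ± 22.8 TPM, and Gapdh was highest at 1306 ± 170 TPM, followed by Aldoa at 1004 ± 123 TPM. Of 4 ketone body genes 3 were detected, among them Acat1 (118 ± 12.1 TPM) and Oxct1 (91.8 ± 24.8 TPM), whereas Bdh1, which interconverts the ketone bodies, was at 0.32 and 0.11 TPM. Ribosomal proteins were detected for 74 of 76 genes, with Rpl41 at 828 ± 99.8 TPM and Rps29 at 627 ± 111 TPM.

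Cell cycle genes were still present at this age. All 20 proliferation genes were detected, at a median of 8.32 ± 1.55 TPM, among them the replication clamp Pcna (28.9 ± 5.23 TPM), the topoisomerase Top2a (23.8 and 16.2 TPM) and Rrm2 (16.9 ± 2.31 TPM). The list of replication-dependent histone genes was drawn by symbol and also took in H1f0, a linker histone outside that class. Its genes were detected for 63 of 68 members (median 44.2 ± 9.52 TPM), led by Hist1h4h at 293 ± 64.4 TPM. Several of them are near-identical copies, so their separate levels are uncertain. Of the cell cycle inhibitors, 6 of 8 were detected, with Cdkn1a highest at 63.7 ± 16.5 TPM, while Cdkn2a (0.37 and 0.16 TPM) and Cdkn2b (0.23 and 0.17 TPM) stayed under 1 TPM. Imprinted genes were detected for 17 of 18 members, and the growth factor Igf2 and the noncoding H19 led them at 277 ± 59.8 and 131 ± 33.6 TPM. All 4 Y-linked genes were detected, as the male sex in the labels requires, with Eif2s3y at 32.0 ± 1.03 TPM. Xist, which silences an X chromosome in females, was at 0.03 TPM in both.

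Among the other cell types of the heart, fibroblast markers had the highest median (125 ± 25.8 TPM), with 13 of 13 detected and Col3a1 at 616 ± 190 TPM, Col1a1 at 327 ± 121 TPM and Col1a2 at 222 ± 75.5 TPM. Endothelial markers (13 of 13, with Fabp4 at 549 ± 165 TPM and Cdh5 at 119 ± 21.3 TPM) and mural cell markers (11 of 11, with Acta2 at 212 ± 63.8 TPM and Rgs5 at 151 ± 11.7 TPM) followed. Macrophage and myeloid markers were detected for 14 of 15 genes, but their median was 2.81 ± 0.0141 TPM, and Lyz2 was highest at 12.1 ± 2.74 TPM. In the other quantification that median was 4.84 ± 0.412 TPM. Red blood cell RNA was present: Hbb-bs was at 4573 ± 673 TPM, and the near-identical Hba-a1 and Hba-a2 were at 3844 ± 7.22 and 3480 ± 108 TPM. The embryonic globin genes Hbb-y and Hba-x were at 0.030 ± 0.0424 and 0.035 ± 0.0495 TPM, and Hbb-bh1 had no counts. Lymphocyte, skeletal muscle, lung and thymocyte markers were scarce, whereas adipocyte markers were abundant in replicate 1, with Ucp1 at 239 TPM there and 5.02 TPM in replicate 2. Of 11 lymphocyte markers 1 was detected (Ighm, 3.10 ± 0.396 TPM), of 14 skeletal muscle markers 1 (Tnni2, 1.52 ± 0.410 TPM), of 7 lung markers 1 (Scgb1a1, 2.66 ± 1.28 TPM) and of 7 thymocyte markers 0, with Lck at 1.61 and 0.58 TPM. In bulk RNA these are levels of transcripts, not shares of cells.

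**Figure D1:**
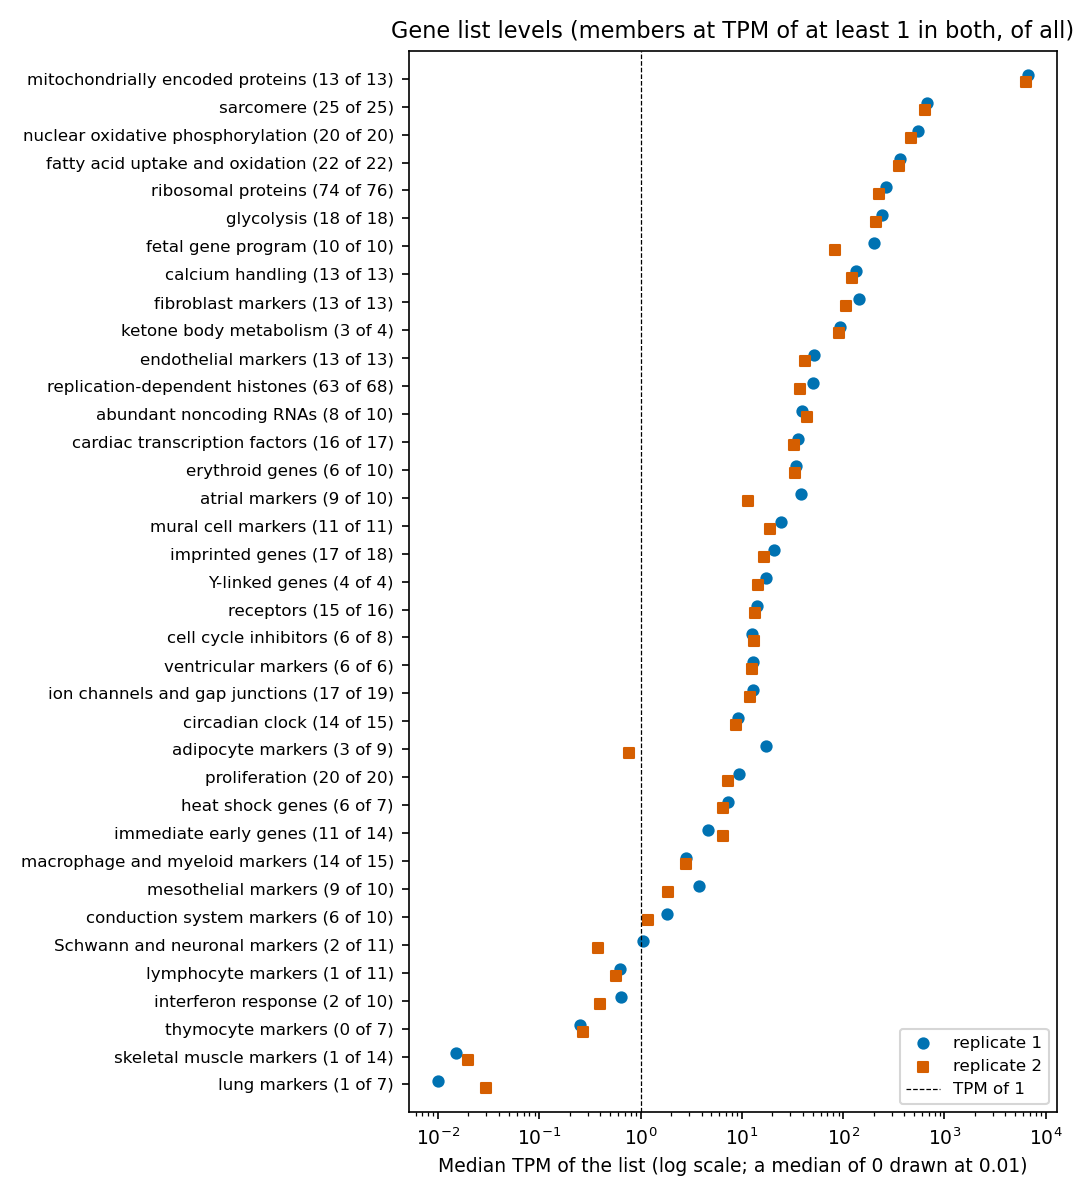
Median TPM (log scale) of the members of each fixed gene list in replicate 1 (circles) and replicate 2 (squares), with the number of members at 1 TPM or more in both libraries and the number of all members beside each name. By ratio, the medians differ most for the adipocyte markers (17.2 and 0.76 TPM), the atrial markers (38.1 and 11.6 TPM), the Schwann and neuronal markers (1.05 and 0.38 TPM), the fetal gene program (203 and 82.7 TPM) and the mesothelial markers (3.75 and 1.87 TPM), apart from the lung markers near 0.

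The next comparison asked, within each animal, how far genes typical of the adult mouse ventricle outweighed their counterparts of the fetal and newborn heart. The adult form was already ahead in most of the 18 pairs. In 14 pairs the adult member was at least 2-fold higher in both animals, in 1 it was at least 2-fold lower, and in 3 the difference was under 2-fold in at least 1 animal. Among contractile genes, the log2 ratio of TPM (pseudocount 0.1) was 3.49 ± 0.02 (SD, n = 2) for Myh6 over the fetal myosin Myh7, 6.20 ± 0.02 for Actc1 over the skeletal actin Acta1, and 3.14 ± 0.27 for the cardiac troponin I gene Tnni3 over the slow skeletal gene Tnni1. Myh7 itself still stood at 752 ± 24.9 TPM and Tnni1 at 274 ± 26.9 TPM.

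The adult member also led in most metabolic pairs. The insulin-responsive glucose transporter Slc2a4 exceeded Slc2a1 by a log2 ratio of 4.39 ± 0.30, the muscle creatine kinase Ckm exceeded the brain form Ckb by 4.74 ± 0.29, and the sarcomeric mitochondrial kinase Ckmt2 exceeded Ckmt1 by 8.97 ± 0.15. Ckmt1 was at 0.61 TPM with only 29 and 14 counts, so the size of the last ratio depends on the pseudocount. Smaller leads were seen for Eno3 over Eno1 (2.85 ± 0.19), Pgam2 over Pgam1 (2.61 ± 0.42), the adenine nucleotide carrier Slc25a4 over Slc25a5 (2.47 ± 0.24), Cpt1b over the liver-type Cpt1a (2.35 ± 0.17), Cox8b over Cox8a (1.53 ± 0.20) and Cox6a2 over Cox6a1 (1.47 ± 0.36). Hexokinase 2 (Hk2) over hexokinase 1 (Hk1) was at -0.47 ± 0.14, Cox7a1 over Cox7a2 at 0.34 ± 0.07 and Ldhb over Ldha at 0.99 ± 0.17, and these 3 pairs were not counted either way. In the growth factor pair the order was the opposite, since Igf1 over the fetal growth factor Igf2 was at -3.96 ± 0.28.

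In 2 pairs the animals disagreed in size. Myl3 over Myl4 was 3.99 in replicate 1 and 6.23 in replicate 2, and Myl2 over Myl7 was 4.33 and 6.43. Myl4 and Myl7 are also atrial genes, whose levels differed between the animals as described below for the atrial markers. An exact 2-sided sign-flip permutation test over 2 animals cannot give a p below 0.5, so no pair was tested.

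**Figure D2:**
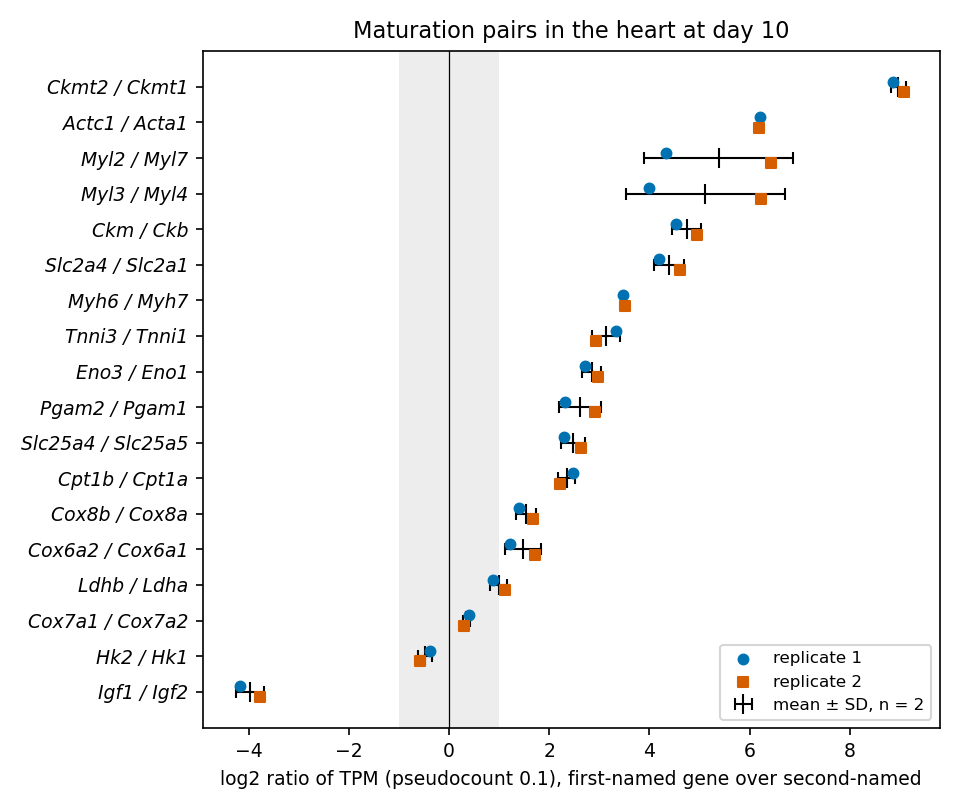
Log2 ratio of TPM, first-named gene over second-named gene, for 18 maturation pairs in replicate 1 (circles) and replicate 2 (squares), with the mean and SD (n = 2) as a bar; the shaded band marks differences under 2-fold. Igf1 over Igf2 lies at -3.96, and the 2 pairs with an atrial light chain, Myl3 over Myl4 and Myl2 over Myl7, show the widest gaps between the animals.

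The hearts were then set against each other. The clearest difference was that replicate 2 held far less RNA of adipocyte genes. All 7 measured adipocyte markers were lower in replicate 2, with a median log2 ratio of -4.85, and for all 7 the exact 95% interval of the ratio left out 1. Ucp1, the uncoupling protein of brown fat (chromosome 8, 83290352 to 83298452), had 11106 counts in replicate 1 and 247 in replicate 2 (log2 ratio -5.35, interval -5.54 to -5.17), a 40.7-fold difference. The carbonic anhydrase Car3 was 52.0-fold lower (2435 and 42 counts), the lipid droplet protein Plin1 30.9-fold lower (1650 and 48 counts) and the adipokine Adipoq 28.8-fold lower (524 and 16 counts). Cidea was 2.91-fold lower, from 82.2 to 24.2 TPM. Leptin (Lep, 4 and 0 counts) and resistin (Retn, 3 and 0 counts) had too few counts to measure.

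Atrial genes were also lower in replicate 2. The 10 atrial markers had a median log2 ratio of -1.49, with 9 lower and 6 of them over 2-fold. Bmp10, a growth factor of the atrial, mainly right atrial, myocardium (chromosome 6, 87428994 to 87437677), had 5857 counts in replicate 1 and 46 in replicate 2, a 114-fold difference (log2 ratio -6.84, interval -7.30 to -6.43). The natriuretic peptide Nppa was 5.57-fold lower (17446 and 2839 counts), the atrial light chains Myl4 and Myl7 4.14-fold and 3.89-fold lower, and sarcolipin (Sln) 3.12-fold lower. Kcna5 went the other way, with a log2 ratio of 0.68. The ventricular markers, 6 genes led by Myl2 and Myl3 (4608 ± 51.4 TPM), had a median log2 ratio of 0.08 and were not apart from random lists. The fetal gene program was apart at -0.33, and its 3 members over 2-fold lower were the atrial genes Nppa, Myl4 and Myl7. Its other members included Nppb at -0.28 and Myh7 at 0.22.

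Other tissue markers moved in the same direction. Of 9 measured Schwann and neuronal markers all were lower in replicate 2 (median -0.72), among them the glial gene S100b (135 and 17 counts, log2 ratio -2.81) and the myelin gene Mbp (373 and 105 counts, -1.68). Mesothelial markers were lower for 9 of 10 genes (median -0.81), with Krt19 2.28-fold, Krt8 1.99-fold and Lrrn4 1.91-fold lower. Conduction system markers were lower for 7 of 9 (median -0.62), with Vsnl1 at 41 and 1 counts (-4.65, interval -10.55 to -2.66), Cpne5 at -1.10 and the sinus node factor Shox2 at -1.07. Fibroblast markers were lower for 12 of 13 genes (median -0.37), with Fbln1 at -0.62, Col1a1 at -0.54 and Col1a2 at -0.53. Macrophage and myeloid markers were lower for 11 of 15 genes (median -0.28), for 7 of them with an interval that left out 1. Their largest negative ratios were those of C1qa (-0.56), Cd68 (-0.56, interval -1.14 to 0.01) and C1qb (-0.49). Endothelial (-0.03) and mural cell markers (-0.03) were not apart, nor were the lymphocyte (-0.19), skeletal muscle (-0.32) and thymocyte lists. The mural median covers unlike members: the smooth muscle genes Tagln (-0.72), Myh11 (-0.66), Cnn1 (-0.63) and Acta2 (-0.42) lay lower than the pericyte genes Pdgfrb (-0.03), Rgs5 (0.06), Kcnj8 (0.11) and Abcc9 (0.15), a split seen afterwards and not tested. Lung markers had fewer than 3 measured genes and were not tested.

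Replicate 2 was higher for immediate early genes, the transcription factors and regulators that switch on within minutes of a stimulus. All 14 lay above replicate 1, at a median log2 ratio of 0.59, and for 10 of them the interval left out 1. Nr4a1 had 460 and 2716 counts (2.70, interval 2.56 to 2.85), Atf3 126 and 496 counts (2.11) and Fosb 19 and 71 counts (2.02), while Egr1 (0.16) and Junb (0.02) hardly differed. The circadian clock list was apart at a median of 0.34, with Hlf at 0.82, Ciart at 0.77 and Per1 at 0.65 against Arntl at -0.51 and Nr1d1 at -0.42, so its members went both ways. Sarcomere genes were higher for 20 of 25 members (median 0.19), with Tcap at 0.65, the giant protein titin (Ttn) at 0.53 and Tnni1 at 0.43. Erythroid genes were higher for 7 of 7 (median 0.25), with Hbb-bs at 0.52 and Hbb-bt at 0.41. Smaller upward shifts were found for the receptors (0.18; Nr3c2 at 0.70, Chrm2 at 0.69, Agtr1a at 0.68), mitochondrially encoded proteins (0.16; mt-Co1 at 0.25, mt-Atp6 at 0.21, mt-Nd5 at 0.19) and fatty acid uptake and oxidation (0.10; Ucp3 at 0.87, Pdk4 at 0.68, Cpt1a at 0.30). Cardiac transcription factors were apart at 0.11, with Hand2 at 0.81, Gata6 at 0.48 and Irx4 at 0.42, but only 2 of the 16 runs that left out 1 member kept them apart. In the other quantification neither they (percentile 96.9) nor the mitochondrially encoded proteins (94.3) stood apart. The sizes of these shifts depend on the scaling. Under totals without mitochondrial genes and spike-ins the median was 0.11 for sarcomere genes, 0.10 for receptors, 0.09 for mitochondrially encoded proteins, 0.03 for fatty acid uptake and oxidation and 0.03 for cardiac transcription factors. In the deposited TPM, the median of the sarcomere list was lower in replicate 2 (668 and 649 TPM), as was that of the mitochondrially encoded proteins (6608 and 6408 TPM), so higher here means relative to other genes under TMM scaling.

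Lists with smaller downward shifts were the replication-dependent histones (-0.27, 58 of 64 genes lower; Hist1h4n at -1.07, Hist2h2aa1 at -0.85, Hist1h1e at -0.65), heat shock genes (-0.25; Hspa1b at -0.50, Hsp90aa1 at -0.27, Hsph1 at -0.25), proliferation (-0.21, 20 of 20 genes lower; Plk1 at -0.43, Cdk1 at -0.38, Aurkb at -0.33), imprinted genes (-0.12; Mirg at -0.64, Dlk1 at -0.46, H19 at -0.30) and glycolysis (-0.08; Pgam1 at -0.69, Hk2 at -0.45, Pfkl at -0.45). The imprinted genes stayed apart in 17 of 18 runs that left out 1 member. Under totals without mitochondrial genes and spike-ins they were at -0.19 and glycolysis at -0.15. No difference from random lists was found for calcium handling (0.11), ion channels and gap junctions (0.10), nuclear oxidative phosphorylation, ribosomal proteins (-0.02), ketone body metabolism (-0.01), cell cycle inhibitors (-0.02), the interferon response (-0.32) or Y-linked genes (0.19). Another scaling of the libraries shifts all list medians alike, and it turned the signs of the nuclear oxidative phosphorylation and thymocyte medians, which lie near 0.

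A list counted as apart had a median log2 ratio outside the central 95% of 10000 random lists of the same size matched on mean expression. Of 36 lists tested, 22 were apart, 13 lower and 9 higher in replicate 2, where 1.8 would be by chance. Genes of a list vary together, which random lists do not reproduce, and each animal has 1 library, so these percentiles describe these libraries and give no p-value.

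**Figure D3:**
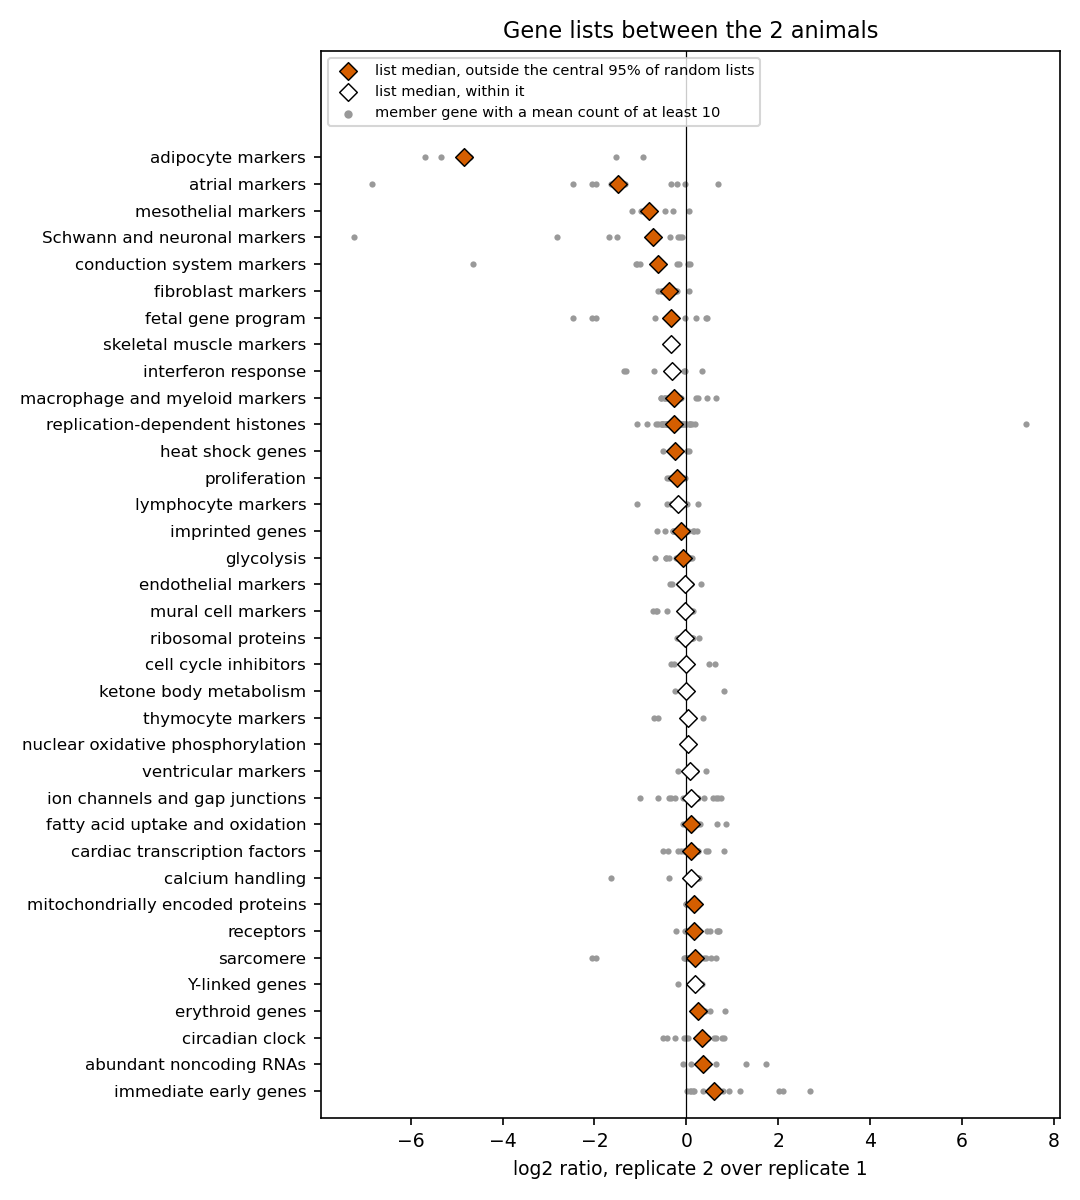
Log2 ratio of replicate 2 over replicate 1 for the measured members (dots) of 36 gene lists and the list medians (diamonds, filled where outside the central 95% of random lists). The adipocyte markers lie lowest with a median of -4.85 and the immediate early genes highest with 0.59; the isolated histone dot on the right is a gene with no counts in replicate 1.

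Over single genes, most of the 2 transcriptomes coincided. Among 13213 genes with a mean count of at least 50, the median absolute log2 ratio was 0.14 and its 95th percentile 0.65. There were 106 genes over 2-fold higher in replicate 2 and 130 over 2-fold lower with an exact interval that left out 1. The other quantification gave 62 higher and 126 lower among 13535 genes, and the numbers below are from the first. Counting noise alone gave 0.25 such genes on average and at most 2 in 100 simulated pairs. With variation between animals added at a coefficient of 0.126, 11 of 13014 simulated unchanged genes were counted. That coefficient was itself estimated from these libraries, over genes with at least 100 counts in both. It lies below the 0.147 found over genes with at least 10 counts, so 11 may be too few. The groups were unlike in kind: the genes higher in replicate 2 included 28 protein-coding genes, 30 of 32 measured snRNA genes, 30 of 247 transcript models of the TEC class and 10 of 28 snoRNA genes. Of the 130 lower, 122 were protein-coding. That is close to the make-up of all 13213 genes compared, of which 12135 were protein-coding, so only the higher group departed from it. After Bmp10, Car3 and Ucp1, low ratios were found for the proton channel Otop1 (314 and 8 counts, -5.07, interval -6.38 to -4.16) and Plin1 (-4.95). Others rested on very few counts in replicate 2. The adipokine Cfd had 123 and 3 counts (interval of the log2 ratio -7.51 to -3.64), and Mmd2 had 122 and 1 counts (-6.21, interval -12.10 to -4.28). The processed pseudogene Gm14760 had 143 and 0 counts, at least 43.2-fold lower against a floor of 3 counts, and Gm14440 had 351 and 1 counts (-7.73, interval -13.62 to -5.83).

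**Figure D4:**
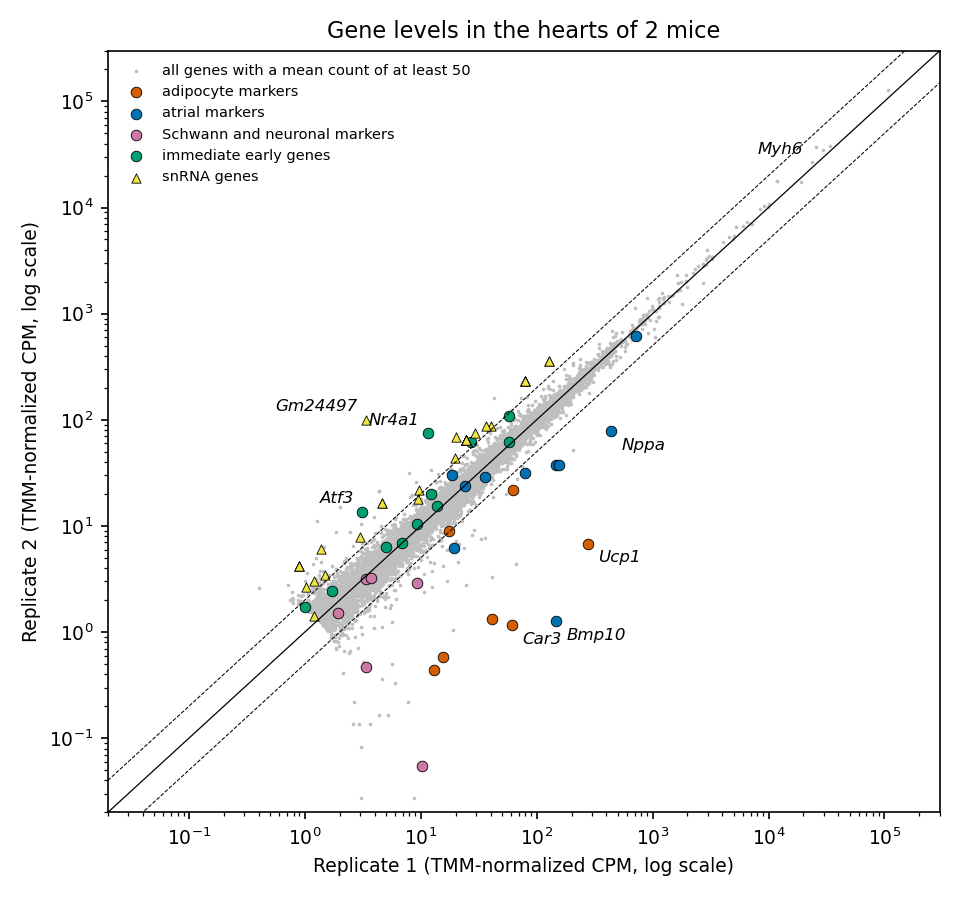
TMM-normalized CPM (counts scaled to library size; log scales) of each gene with a mean count of at least 50 in replicate 1 (horizontal) and replicate 2 (vertical), with a solid line at equality and dashed lines at 2-fold; genes with no counts in either one of the libraries are not drawn. Ucp1, Car3, Bmp10 and Nppa lie below the lower dashed line, and Nr4a1, Atf3 and most snRNA genes above the upper one.

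Short noncoding RNAs of several classes were more abundant in replicate 2, though the 8 genes of the scaRNA class hardly differed (median log2 ratio 0.06). The share of snRNA genes, the RNA components of the spliceosome, was 0.0967% of counts in replicate 1 and 0.257% in replicate 2, that of snoRNA genes 0.0417% and 0.0687%, and that of the misc_RNA class, to which Rn7s1 and Rn7sk belong, 2.97% and 3.93%. The median log2 ratio was 1.40 over 32 snRNA genes and 0.82 over 28 snoRNA genes. Copies with identical counts in both libraries entered these numbers more than once. Counted once each, 19 snRNA measurements remained, of which 17 were over 2-fold higher (median 1.36), and 22 snoRNA measurements, of which 7 were (median 0.78). The list of abundant noncoding RNAs was apart at 0.36, though not in the other quantification (0.31, percentile 96.5), with Rpph1, the RNA of ribonuclease P, at 0.65 (6314 ± 1300 TPM), Malat1 at 0.34 (2334 ± 116 TPM) and Neat1 at -0.08. These TPM levels do not hold in the other quantification, where the whole list had 0.137% of TPM, against 3.86% in the first. The largest ratios of the list rested on few counts: Xist had 5 and 16 counts (1.73), and Snord118 had 6 and 14 (1.30, interval -0.11 to 3.03). Several genes at the top of the ratios belong to families whose copies share reads. The U3 RNA genes Rnu3b1, Rnu3b2 and Rnu3b4 all had 174 and 772 counts (2.29), and the snRNA gene Gm24497 had 136 and 3634 counts (4.88). Rnu3a was listed as 2 entries at the same locus on the plus strand of chromosome 10. The entry from 40258467 to 40258680 had 0 and 624 counts, at least 229-fold higher against the floor. The entry from 40258467 to 40258679 had 228 and 18 counts (-3.49). Reads of this locus could be assigned to either entry, so neither ratio can be read as the change of a separate gene. The protein-coding gene 1700047I17Rik2 had 0 and 184 counts, at least 67.6-fold higher, and the remaining top genes were the TEC models Gm42614 (3.12) and Gm42615 (2.89) and the pseudogene Gm15899 (2.66). These copy-bearing genes are reported as uncertain.

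The spike-ins bear on the comparison of the libraries. Of 96 ERCC controls, 73 had counts in replicate 1 and 70 in replicate 2, and together they held 0.576% and 0.562% of the counts. Relative to the scaling by genes, the 34 controls with a mean count of at least 50 had a median log2 ratio of 0.07, with a range from -0.22 to 0.23. Nuclear protein-coding genes held 67.4% of counts in replicate 1 and 64.7% in replicate 2.

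Transcript usage was examined for 22 genes with known cardiac splicing. The same transcript was dominant in both animals for 19 genes, and its share was at least 50% in 11. Titin was led by Ttn-201 with 37.8% ± 2.00 of the gene's TPM (SD, n = 2), followed by Ttn-215 with 29.4%, and the tropomyosin gene Tpm1 by Tpm1-205 with 96.1% ± 0.718. Camk2d-202 held 50.6% ± 1.31 of Camk2d, Camk2g-203 21.7% ± 1.54 of Camk2g and Actn1-201 49.8% ± 0.128 of Actn1. In the other quantification these transcripts also led, but Ttn-215 had 17.9%, Tpm1-205 71.3% ± 0.253 and Camk2d-202 38.4% ± 2.32. The leading Cacna1c transcript, with 41.0% ± 0.803, was Cacna1c-218, annotated as a processed transcript and not as coding for the calcium channel. Its share was 28.8% ± 0.994 in the other quantification.

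For 8 of the 22 genes the dominant transcript differed between the deposited quantifications of the same libraries. Pkm was split almost evenly, with Pkm-202 at 48.6% ± 0.0228 and Pkm-201 at 48.4% in the first quantification and Pkm-201 leading at 47.9% ± 0.516 in the second. Cardiac troponin T (Tnnt2) was led by Tnnt2-211 (42.0% ± 0.787) in the first and by Tnnt2-209 (58.7% ± 2.05) in the second, Mef2c by Mef2c-212 (20.8% ± 1.74) and Mef2c-201 (16.3% ± 4.25), and fibronectin (Fn1) by Fn1-208 (23.8% ± 1.24) and Fn1-203 (27.8% ± 0.00192). The others were Slc8a1, Nexn, Pdlim5 and Rbfox1. At the level of genes, log2(TPM + 1) of the quantifications correlated with Pearson coefficients of 0.954 and 0.947 across genes in replicates 1 and 2, and 4.87% and 7.37% of protein-coding genes at 1 TPM or more in either one differed over 2-fold.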

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

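Scaling by DESeq2 size factors, totals without mitochondrial genes and spike-ins, or spike-in totals shifts all genes by 1 constant, so it cannot move a list's place among random lists and says nothing about the 22 lists that stood apart. In the other quantification 19 of them stood apart, while cardiac transcription factors, mitochondrially encoded proteins and abundant noncoding RNAs no longer passed. At a mean count of at least 50, cardiac transcription factors no longer passed either (percentile 97.1). The number of genes over 2-fold moved more. Higher in replicate 2 were 62 genes in the other quantification, 459 with no filter on counts, 48 at a mean count of at least 200 and 28 among protein-coding genes only, an alternative chosen after seeing the data, against 106. Lower were 462 with no filter and 52 at a mean count of at least 200, against 130. The number of genes entering does not alone account for these numbers, since the share over 2-fold also changed. It was 1.79% of 13213 genes in the main setting. With no filter it was 1.66% of all 55536 annotated genes. Only 26007 of these had a count above 0 and could be called, so that share cannot be set against the others. At a mean count of at least 200 it was 0.98% of 10209 genes, and among protein-coding genes 1.22% of 12135. The cause of the difference between quantifications was not tested. Of the correlations between animals, Pearson's fell to 0.979 and Spearman's rose to 0.978 over genes at 1 TPM or more in either library, since genes near 0 were left out. The coefficient of variation was 0.126 over genes with at least 100 counts in both. As shares of TPM in place of counts, mitochondrial genes held 25.2%, the 10 most abundant genes 39.8% and spike-ins 0.896%; TPM weighs short RNAs more by construction. Leaving out each replicate gave 13004 to 13308 detected genes, 477 to 492 detected list members (473 of 564 in both), 14 to 15 pairs with the adult member higher, 10 to 11 isoform genes with a share of at least 50%, 22.6% to 24.2% of counts in mitochondrial genes, 29.2% to 32.4% in the 10 most abundant genes and 0.562% to 0.576% in spike-ins. No paired analysis was possible because there was 1 group. With 2 animals, leaving out 1 cannot move a mean by its SD, so the ranges without each replicate test nothing, and FPKM keeps the ratio within a pair apart from the pseudocount. By more than the SD between animals, 11 of the 18 pairs moved in the other quantification, 12 in CPM without length scaling and 2 with a pseudocount of 1. Of the list medians, 29 moved in the other quantification and 30 on rescaling without mitochondrial genes and spike-ins. Median TPM moved by over 1.5 times in the other quantification for nuclear oxidative phosphorylation (885, against 509), ribosomal proteins (401, against 245), the fetal gene program (238, against 143), imprinted genes (28.8, against 18.6), adipocyte markers (14.2, against 8.98), macrophage and myeloid markers (4.84, against 2.81), thymocyte markers (0.412, against 0.260), skeletal muscle markers (0.147, against 0.0175) and abundant noncoding RNAs (0.396, against 41.9). The cause was not tested. Rescaling TPM to nuclear protein-coding genes, chosen after seeing the data, raised 35 list medians by construction through its smaller denominator, to 1643 for sarcomere genes (against 659) and 904 for fatty acid uptake and oxidation (against 362). Depth limits statements on genes with few counts: at these totals, 3 counts equal 0.0772 and 0.0791 CPM.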

Other observations

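For the patterns below, the test of counting noise and scaling for adipocyte genes and the test of RNAs under 300 nt were chosen only after the result was seen. The labels give 1 group, so no biological explanation that rests on a difference between groups was tested.

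The members of a second adipocyte list, written to test the adipocyte pattern, differed widely. Elovl3, which elongates fatty acids in brown fat, had 55 counts in replicate 1 and 1 in replicate 2 (log2 ratio -5.07, interval -10.97 to -3.10), the adipogenic factor Cebpa 424 and 86 counts (-2.15), the glycerol phosphate dehydrogenase Gpd1 8197 and 1894 counts (-1.97) and the beta-3 adrenergic receptor Adrb3 19 and 1 counts (-3.56, interval -9.48 to -1.45). Dgat2 (84.4 and 72.9 TPM, 0.02), Kcnk3 (76.6 and 58.3 TPM, -0.27), Aqp7 (14.6 and 13.6 TPM, -0.01) and Prdm16 (8.66 and 8.27 TPM, 0.23) differed less.

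The adipocyte markers were lower in replicate 2 by a median log2 ratio of -4.85. Counting noise or the scaling of the libraries is argued against, since 7 of the 9 markers had an interval below a ratio of 1 under every scaling and in the other quantification. A candidate explanation is brown adipose tissue collected with the heart of replicate 1. The second list held 14 genes, with none from the first and none of those seen with the largest ratios in the first look. It may therefore understate the fall of adipocyte genes. Its median log2 ratio was -0.319, with 12 members lower and a median below all 10000 random lists. This fell between the bounds set beforehand, -1 or lower for fat tissue and above -0.3 against it, and expression of 12 of the 14 genes at 1 TPM or more in replicate 2, which held little fat RNA, keeps the explanation open.

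The atrial genes were lower in replicate 2 while the ventricular markers differed little. A ventricular stress response that differs between the animals is argued against as the cause of the whole fall: Nppb, Acta1, Myh7, Tnni1, Ankrd1 and Xirp2 had a median log2 ratio of 0.098 and went both ways, from -0.69 for Ankrd1 to 0.46 for Xirp2. Slc2a1, a further member of the fetal program outside the atrial list, was not in this set and was at -0.38. Less atrial tissue in the library of replicate 2 is a candidate explanation, raised by Nppa and Bmp10, and the other 8 members of the same list had a median of -0.831, with 7 lower. The sinus node genes had a median of -0.819 over 6 measured genes, 5 of them lower, which is consistent with a loss that included the sinus node region, although all of them belong to the conduction list, so the median of that list (-0.62) is not separate evidence, and the sides of the atria were not compared. Adipocyte, Schwann, mesothelial and fibroblast markers were lower in the same library, and whether 1 difference in dissection at the base of the heart covers all of them was not tested.

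Short noncoding RNAs were higher in replicate 2, by a median log2 ratio of 1.36 over 47 genes of 100 to 200 nt, 0.82 over 21 of 200 to 300 nt and 0.58 over 7 of 300 to 500 nt. Shorter fragments kept in that library are argued against for RNAs of 300 to 500 nt, since 110 protein-coding genes under 500 nt had a median of -0.019. For RNAs under 300 nt they may still account for the rise, and only 4 protein-coding genes were there to compare (median 0.141). Medians were larger in the shorter bins, but the bins mix different RNA classes and count identical copies more than once. The 8 genes of the scaRNA class had a median of only 0.06, so length was not told apart from class. Reads divided among near-identical copies were tested with 13 genes without a copy of the same name. Their median was 0.648, with 2 of them lower, so most genes without a named copy rose too. That median equals the ratio of Rpph1, which had been seen before the test, as had Snora23. Copies under other names were not looked for, so the test cannot decide whether shared reads are the whole source. A difference in how well small RNAs were recovered during purification, or in the nuclear share of the RNA, was not tested.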
